A study of Leishmania donovani with 3 samples.

How the data were processed

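RibOxi-seq libraries were measured from total RNA of 3 samples of L. donovani strain LD1S promastigotes, all in 1 group. Per the labels' protocols, RNA was broken with Benzonase, taken through repeated oxidation, β-elimination and dephosphorylation, and made into libraries by the rRNA version of an updated RibOxi-seq protocol. Per the submitters' processing notes, cutadapt 2.10, STAR 2.7.5c, SAMtools, UMI-tools 1.01 and bedtools 2.29.2 were used, with no role or order named. How they were set, and which rRNA sequence reads were aligned to, is not given in the sources used here. If UMI-tools served to remove PCR copies, a count is close to a molecule; whether it did is not stated.

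The authors deposited a table of raw counts of fragment ends per rRNA position, with 1 column per sample, per the file headers. The values are whole numbers that sum to 237372, 243646 and 231179, and positions without an end in any library are left out of the table. Those 31 positions were set to 0 in every library. The authors also deposited 1 mean score per position, which is a ratio. Its formula is not stated, and was recovered from the counts: the count divided by the mean of the nearest listed position on each side plus 1, per library, then averaged over the 3 libraries. This returned all 5565 deposited values within 0.01%, with the single neighbour used at the first and last listed position of each molecule. Because the score looks at listed positions only, an unlisted position is skipped, not read as 0. The score has no SD of its own. The counts carry no depth of coverage, so the share of molecules methylated at a site cannot be computed from them, and no unoxidised or mock library was analysed here.

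For each position and library the background was the median count of the 6 positions on each side in the same molecule plus 1 count; at the ends of a molecule only the positions on hand were used. Positions with a mean count of 10 or more were tested. The counts as deposited were fitted with edgeR 4.0.16 in R 4.3.3, with the log background as offset and an intercept only, and the intercept was tested with the quasi-likelihood statistic, one-sided, against a 4-fold minimum. The functions glmTreat and glmQLFTest need at least 2 design columns, so their statistic was written out for the intercept alone: the difference of the deviances at the fitted and the minimum fold over the squeezed quasi-dispersion, with edgeR's Poisson bound. A site was called at a Benjamini-Hochberg adjusted p under 0.05 with 4-fold or more in each library. Folds are the fitted intercepts, with their quasi-likelihood standard errors. The background counts as known in this model, and unevenness between neighbouring positions that repeats in every library, such as a cutting or ligation preference, is not separated from methylation.

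The fit was tested on simulated data drawn from the means and library sizes of the real positions. Positions at 4-fold or more in every library were first set to their background, and 200 positions were then set to a known fold. Of 4036 simulated positions tested, the fit called 99 of 100 set to 8-fold, 50 of 50 set to 16-fold, 0 of 50 set to 2-fold and 14 of 3836 without a set fold, for the comparison of sites with their flanks. The last group kept uneven real means, so its calls are not a clean false positive rate. Set folds were placed only where the background was not thin, so recovery at sites with few flanking ends was not measured. DESeq2 called 100, 50, 0 and 26 of these groups, yet fewer sites than edgeR in the real counts (182 against 280). The simulation does not reproduce that difference.

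Sites named in the text followed a rule fixed before the data were examined: the 20 called sites with the largest fold, the 3 largest in each molecule, the 10 highest deposited scores and the 5 highest mean counts, 27 sites in all; the rule also held 2 conserved loci that could not be located here. Any other site is said to have been picked after its values were seen. Sites per molecule were compared by two-sided Fisher's exact tests. The analyses planned for the base at the site and for 2 conserved loci located by sequence were not run, because they need the rRNA sequence. Alternatives were limma 3.58.1 on log2 ratios with a pseudocount of 1, DESeq2 1.42.0 with the background as normalization factors, no minimum count or one of 50, flanks of 3 or 12 positions, the mean of the flanks, adjacent positions left out, minimum folds of 2 and 8, 5 counts added to the background, each replicate left out, and edgeR's TMM or DESeq2 size factors for the correlations. Correlations used log2 counts scaled to the library total plus 1. Random placements and intervals used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and figures matplotlib 3.10.9.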

Results

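Ribosomal RNA of Leishmania donovani, the kinetoplastid parasite that causes visceral leishmaniasis, was profiled for 2′-O-methylation, the methyl group that small nucleolar RNA-guided enzymes place on the ribose of chosen nucleotides. The cells were promastigotes, the flagellated stage of the sand fly, which grows in culture. RibOxi-seq reads out where fragment 3′ ends lie after randomly broken RNA has been oxidised: an end with a free 2′ hydroxyl is eaten back by cycles of oxidation and β-elimination, and an end that carries a 2′-O-methyl group resists, so resistant positions collect ends. The series held 3 libraries of 1 group, and the labels name no second group to set them against. The question was therefore which rRNA positions gathered more 3′ ends than the positions around them, and how well the 3 libraries repeated each other. Nothing in the labels says whether the libraries came from separate cultures, so the p-values of the site calls measure only the spread between these libraries, which may be technical.

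The table covered 4 rRNA molecules, called 5.8S, SSU, LSU5 and LSU3 in the file. The large subunit rRNA of trypanosomatids is made as several pieces, and the sources used here do not define the names LSU5 and LSU3 further. The libraries held 237372, 243646 and 231179 counted ends in replicates 1, 2 and 3. Of the 5596 positions between the first and last listed position of each molecule, 5565 had at least 1 end in some library. The median listed position held 21, 21 and 20 ends. A count of 0 in a library allows a share of up to 0.00126%, 0.00123% and 0.0013% of its ends in replicates 1, 2 and 3. Such limits, and the intervals below for the share of ends in called sites, cover counting error only. The other intervals below run over positions or sites, which they treat as independent. SSU took 38.2% ± 0.113 of the ends (SD, n = 3), LSU5 34.4% ± 0.0713, LSU3 25.1% ± 0.199 and 5.8S 2.25% ± 0.0179. Positions are counted along each molecule as in the authors' table. Bases and genome coordinates are not given here, because no rRNA sequence was among the sources used.

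A set of 280 positions stood out, each with more than 4 times the ends of its surroundings in all 3 libraries. These sites made up 6.89% of the 4062 positions deep enough to test and 5.03% of all listed positions. They held 33.4% ± 0.661 of all ends (SD, n = 3), a share that is high in part because sites were called for high counts. The strongest was LSU3 position 1385, with 1039 ± 49.1 ends per library (SD, n = 3) against a flank median of 3, 5 and 5 in replicates 1, 2 and 3, a 201-fold excess. SSU position 1833 followed at 200-fold, LSU3 position 1398 at 189-fold, LSU3 position 604 at 165-fold and LSU3 position 534 at 154-fold. The order of LSU3 position 1385 and SSU position 1833 is not settled. Their log2 folds were 7.46 and 7.76 without replicate 1, 7.71 and 7.36 without replicate 2, and 7.76 and 7.78 without replicate 3. Among the called sites, 178 were at 8-fold or more, 96 at 16-fold or more, 51 at 32-fold or more and 12 at 100-fold or more. The median was 10.0-fold and the smallest excess called was 5.07-fold. Each call rested on edgeR's quasi-likelihood test of the counts against a 4-fold minimum over the median of the 12 flanking positions, with a Benjamini-Hochberg adjusted p under 0.05. By the same test, 322 positions had an unadjusted p under 0.05 above 4-fold, a count that also drops the condition on each library. In the other direction, 0 positions were called at a 4-fold deficit by edgeR or by limma, and 5 and 3 positions had an unadjusted p under 0.05; DESeq2 was run for excesses alone. That count of 0 depends on the setting, with 26 positions called at a deficit without a minimum count and 4 with flanks of 3 positions. The count minimum holds it down by construction: a tested position has a mean of 10 ends or more, so a 4-fold deficit needs dense flanks. The size of the set follows the setting: a 2-fold minimum gave 758 sites and 125 positions below their flanks, an 8-fold minimum gave 136 sites, DESeq2 at the 4-fold minimum gave 182, and the mean of the flanks in place of the median gave 159 sites and 89 positions below their flanks.

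**Figure D1:**
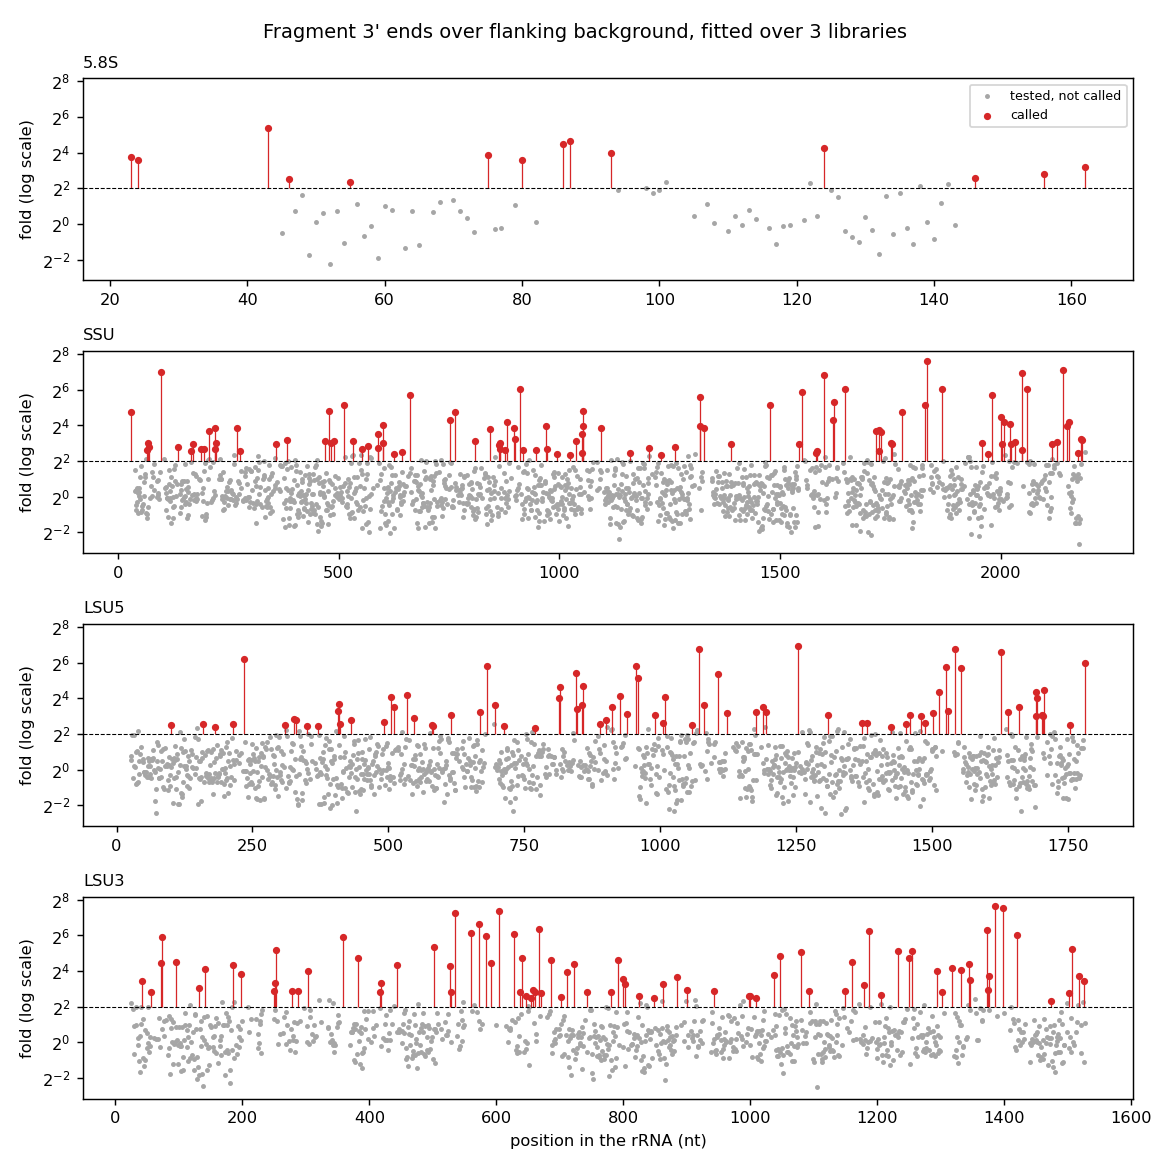
Fitted fold of the 3′ end count over the flanking background (log scale, n = 3 libraries) against the position in the rRNA in nucleotides, for 5.8S, SSU, LSU5 and LSU3. Red stems mark the 280 called sites, grey points the other tested positions, and the dashed line the 4-fold minimum; LSU3 position 1385 is the highest point at 201-fold.

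In SSU, the RNA of the small subunit, which reads the messenger RNA, 104 sites were called and 30 of them were at 16-fold or more. SSU position 1833 held 795 ± 39.2 ends per library (SD, n = 3), and its log2 fold was 7.65 ± 0.15 (SE; edgeR adjusted p = 1.4e-16). The size of that adjusted p depends on the setting. With edgeR it was 6.8e-08, 1.3e-46 and 9.6e-07 without replicates 1, 2 and 3, and with limma 3.9e-08. The site was called each time, but the exponent is no measure of its strength. SSU position 2140 took 0.243% ± 0.00612 of a library and stood at 140-fold, and SSU position 98 held 640 ± 22.1 ends and stood at 128-fold. SSU position 2048 stood at 125-fold with 912 ± 13.0 ends. SSU position 1599 had the highest count of any position, 1456 ± 54.2 ends or 0.613% ± 0.0179 of a library, and stood at 115-fold. SSU position 1979, with 1380 ± 57.0 ends, and SSU position 1478, with 1070 ± 105 ends, lay in denser stretches and stood at 52.1-fold and 35.1-fold. SSU position 912 stood at 66.8-fold with 1029 ± 41.8 ends.

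In LSU5, 77 sites were called and 24 were at 16-fold or more. LSU5 position 1253 led with 1311 ± 79.0 ends per library (SD, n = 3) and a log2 fold of 6.93 ± 0.12 (SE; edgeR adjusted p = 5.4e-17). That edgeR adjusted p was 3.3e-08, 5.0e-48 and 9.6e-07 without replicates 1, 2 and 3. LSU5 position 1542, at 949 ± 59.8 ends, and LSU5 position 1071, at 1171 ± 53.5 ends, stood at 110-fold and 107-fold. LSU5 position 1628 stood at 98.8-fold, LSU5 position 235 at 73.7-fold and LSU5 position 1554 at 51.1-fold. Their counts were 605 ± 61.9, 827 ± 10.8 and 680 ± 96.2 ends.

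In LSU3, 85 sites were called and 38 were at 16-fold or more. Besides the 4 leading sites above, LSU3 position 572 stood at 99.2-fold with 719 ± 30.4 ends per library (SD, n = 3). LSU3 position 667 stood at 81.5-fold, LSU3 position 1373 at 78.4-fold and LSU3 position 1186 at 76.6-fold. LSU3 position 560 stood at 71.5-fold on 233 ± 37.8 ends, and LSU3 position 628 at 68.2-fold on 1008 ± 86.4 ends. The sites took 45.6% ± 0.947 of the ends of LSU3, against 38.1% ± 0.904 in 5.8S, 31.2% ± 0.46 in SSU and 26.6% ± 0.664 in LSU5. These shares are not adjusted for the background, whose median flank was 15.0 ends in LSU3 and 26.0 in LSU5. They cannot be read as a trait of a molecule apart from its background.

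In 5.8S, the short rRNA that pairs with the large subunit RNA, 14 sites were called and 4 were at 16-fold or more. The largest excess was at 5.8S position 43, with 66.7 ± 9.5 ends per library (SD, n = 3) and 41.9-fold. Its call ended when the adjacent positions were left out of the flanks, where the log2 fold was 2.21, and when the mean of the flanks was used, where it was 0.67. Neighbouring 5.8S positions 86 and 87 held 74.3 ± 9.02 and 82.7 ± 7.02 ends and stood at 22.7-fold and 24.9-fold, with edgeR adjusted p of 2.1e-09 and 7.5e-11. Without replicates 1, 2 and 3 the edgeR adjusted p of position 86 was 6.3e-06, 5.2e-15 and 3.4e-04. That of position 87 was 6.1e-06, 7.7e-18 and 3.5e-05. Position 86 also lost its call with the mean of the flanks, at a log2 fold of 1.85. With 5 counts in place of 1 added to the background, the log2 folds of positions 43, 87 and 86 were 3.56, 3.49 and 3.35, against 5.39, 4.64 and 4.5, and all 3 were still called. These 3 sites, named for their fold, lay on thin flanks. 5.8S position 124, picked after its values were seen, held more ends, 800 ± 48.8 per library, and stood at 19.5-fold. Its folds under the other settings are not given here.

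The largest folds carry an uncertain denominator, because their flanks held few ends. When 5 counts in place of 1 were added to the background, the fold of LSU3 position 1385 became 112, and 13 of the 20 sites with the largest fold moved by more than 1.5 times. With the mean of the flanks 8 of the 20 moved that far, and with flanks of 3 or of 12 positions 4 each. The log2 fold of SSU position 1833 was 5.34 with the mean, against 7.65, and that of LSU3 position 534 was 5.87 with 12 positions, against 7.27. All 20 were still called under these 4 settings.

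**Figure D2:**
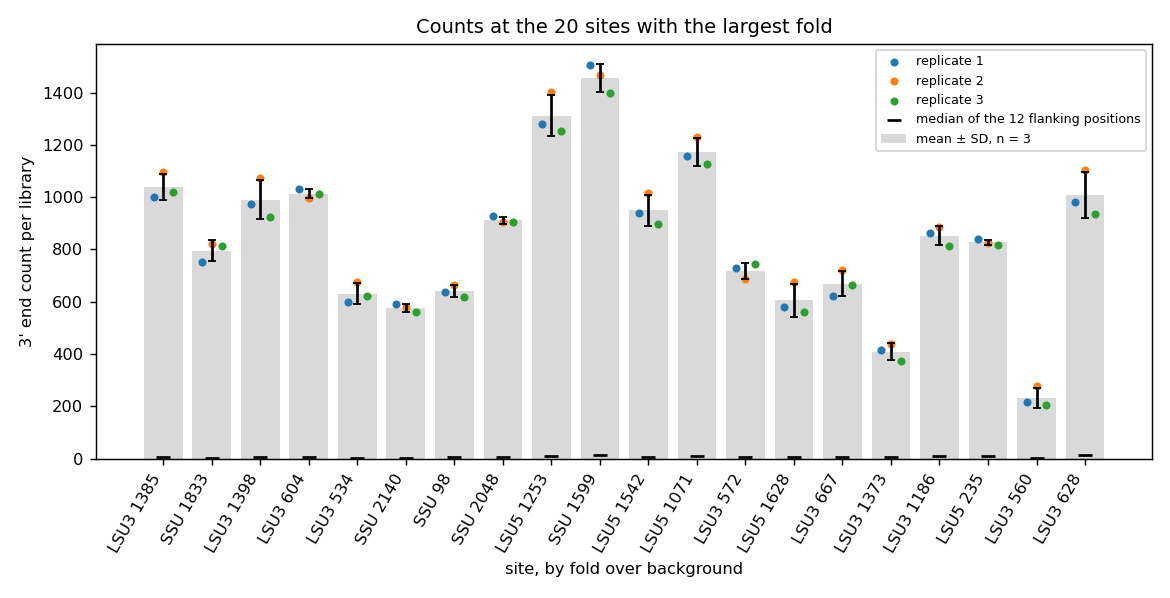
Number of fragment 3′ ends per library at the 20 sites with the largest fold, ordered by fold; bars are means with SD (n = 3), points the replicates and short black lines the median of the 12 flanking positions. Counts run from 233 ends at LSU3 position 560 to 1456 at SSU position 1599, with all flank medians near the bottom of the axis.

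The density of sites differed between the molecules when set against the tested positions. Of the tested positions, 17.3% were called in 5.8S (14 of 81), 8.74% in LSU3 (85 of 973), 6.43% in SSU (104 of 1617) and 5.54% in LSU5 (77 of 1391). Against the rest of the rRNA, two-sided Fisher's exact tests gave odds ratios of 2.92 for 5.8S (adjusted p = 0.0043), 1.42 for LSU3 (adjusted p = 0.018), 0.712 for LSU5 (adjusted p = 0.018) and 0.886 for SSU (adjusted p = 0.38), over 4 comparisons. These tests run over positions, whose flanks overlap, and treat them as independent. With all positions of the span as the denominator, an alternative chosen after seeing the data, no molecule passed: the odds ratios were 2.12, 1.19, 0.817 and 0.921 for 5.8S, LSU3, LSU5 and SSU, with exact adjusted p of 0.068, 0.25, 0.25 and 0.53. The 5.8S excess turned with the mean of the flanks, to an odds ratio of 0.943, and LSU5 lost its call without replicate 1, at 0.763 (exact adjusted p = 0.077). LSU3 lost its call at a 2-fold minimum (1.15, exact adjusted p = 0.17) and 5.8S at a mean count of 50 or more (1.84, exact adjusted p = 0.23), and with no minimum count 5.8S, LSU3 and LSU5 all lost theirs (2.19, 1.19 and 0.83). Other settings moved away from 1. LSU3 rose to 2.2 at a mean count of 50 or more, 1.98 with the mean of the flanks and 1.89 at an 8-fold minimum (exact adjusted p = 4.6e-06, 3.5e-04 and 0.0027). LSU5 fell to 0.547, 0.657 and 0.581 under the same settings (exact adjusted p = 8.8e-05, 0.043 and 0.01). With the tested positions stratified into 10 groups by background, the odds ratio of LSU3 was 1.0 (95% interval 0.763 to 1.32).

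Counts correlated between the 3 libraries. Across the tested positions, which are not independent replicates, Pearson's r of log2 counts was 0.94 between replicates 1 and 2, 0.944 between 1 and 3 and 0.943 between 2 and 3, and Spearman's rho was 0.921, 0.925 and 0.923. The median coefficient of variation of the share of the library was 15.2% at the tested positions. Single libraries placed 409, 421 and 425 tested positions at 4-fold or more, and 328 of the 525 positions found in any library were found in all. Chi-square of the counts per degree of freedom was 1.35 for replicates 1 and 2, 1.14 for 1 and 3 and 1.22 for 2 and 3, where counting noise of independent molecules alone gives about 1 and PCR copies would add to it. The 3 libraries were counted as separate samples. The called sites took 32.7% of the ends in replicate 1 (95% Wilson interval 32.5 to 32.9), 34.0% in replicate 2 (33.8 to 34.2) and 33.4% in replicate 3 (33.2 to 33.6).

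The authors' deposited mean score was set against the fold. This score is a ratio of the count at a position to the mean of its nearest listed neighbours plus 1, averaged over the libraries by the authors. The highest score, 230, fell on LSU3 position 1385, followed by 194 at LSU3 position 604, 193 at LSU3 position 534, 187 at LSU5 position 1628 and 170 at SSU position 1833. LSU5 position 1554 scored 168, SSU position 912 156, SSU position 98 155, SSU position 2140 139 and SSU position 1599 137. Other sites ranked apart: SSU position 2048 was 8th by fold and 36th by score, LSU3 position 1373 16th and 76th, LSU3 position 560 19th and 52nd, and LSU5 position 1554 36th and 6th. The 100 positions with the highest score were all among the 280 called sites. Spearman's rho between score and fold was 0.721 across the tested positions, which are not independent. Both measures divide the same counts, and their denominators share the adjacent positions, so part of this relation and of the overlap is built in. Of the 280 called sites, 188, or 67.1%, were among the 280 highest scores (95% Wilson interval 61.4 to 72.4). The neighbouring 5.8S positions 87 and 86, each of which is part of the other's denominator, were among the 92 outside, with deposited scores of 2.17 and 1.75 that ranked 914 and 1211.

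**Figure D3:**
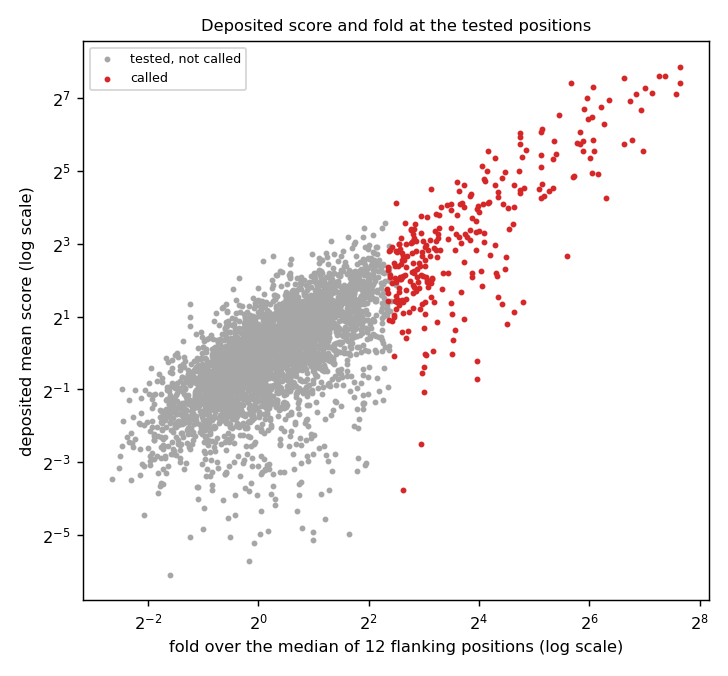
Deposited mean score (log scale) against the fitted fold over the median of 12 flanking positions (log scale) at the 4062 tested positions, with the 280 called sites in red. Score and fold rose together (Spearman's rho 0.721 across positions).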

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

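The alternatives with all positions as denominator and with unlisted positions read as 0 in the score were chosen after seeing the data. The number of called sites, 280, stayed within 1.5 times under limma (267), no minimum count (276), a mean count of 50 or more (279), flanks of 3 (232) or 12 positions (322), adjacent positions left out (305) and 5 counts added to the background (221), and ran from 236 to 263 with 1 replicate left out. It moved further with DESeq2 (182), the mean of the flanks (159), and minimum folds of 2 (758) and 8 (136); the last 3 change the size asked for, or let other sites enter the background, by construction, and the cause under DESeq2 was not tested. All 182 DESeq2 sites, all 159 of the mean and all 136 at 8-fold were among the 280. For the odds ratios per molecule, LSU3 lost its call at a 2-fold minimum (1.15) and with no minimum count (1.19), where 5.8S (2.19) and LSU5 (0.83) lost theirs too. LSU3 rose to 2.2 at a mean count of 50 or more, 1.98 with the mean of the flanks and 1.89 at an 8-fold minimum. LSU5 fell to 0.547, 0.657 and 0.581 under the same settings. 5.8S lost its call at a mean count of 50 or more (1.84) and turned with the mean of the flanks (0.943). With all positions as denominator none of these 3 kept its call (5.8S 2.12, LSU3 1.19, LSU5 0.817). The called sites are the same there, so that loss comes from the denominator alone. The share of positions tested was 56.6% in 5.8S, 64.5% in LSU3, 74.1% in SSU and 78.9% in LSU5. For the other lost calls the cause was not tested. Leaving out 1 replicate gave 2.29 to 3.07 for 5.8S, 1.41 to 1.63 for LSU3, 0.812 to 0.922 for SSU and 0.638 to 0.763 for LSU5, which lost its call without replicate 1 (exact adjusted p = 0.077). The mean Pearson r between libraries was 0.942 under both scalings and without a minimum count, and 0.962 at a mean count of 50 or more. The overlap of sites with as many top scores, 67.1%, ran from 62.7% to 72.0% with other flanks from 67.4% to 69.1% without 1 replicate, and was 67.1% with unlisted positions read as 0. For the 27 named sites, 375 of 378 values under the alternatives kept direction and call. The other 3 are those given for 5.8S positions 43 and 86. Most of these sites were named for large folds, scores or counts, so a kept call was likely from the start. Changing the count minimum or the minimum fold leaves the background as it is, so the folds there hardly could move. The 375 therefore say little about weaker sites. They do not cover the size of the adjusted p, which moved by orders of magnitude when 1 replicate was left out. The 1534 positions under the count minimum were not tested with it; without it 5565 positions were tested, and all 276 sites were among the 280. Positions called below their flanks numbered 0 with the settings of the report, 89 with the mean of the flanks, 26 without a minimum count, 125 at a 2-fold minimum, 4 with flanks of 3 positions, and 1 each with 5 added counts and without replicate 2. The alternatives planned for the base at the site were not run, for want of the rRNA sequence. No paired analysis was possible because the study has 1 group.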

Other observations

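All patterns here were noticed in the data, and the tests of adjacent pairs, of a shoulder and of the last positions of the other molecules were chosen after the results they measure were seen. Several sites lay side by side. The 280 calls held 18 directly adjacent pairs, and these pairs, picked after their values were seen, include positions that the deposited score ranks low because each neighbour is the other's reference. SSU position 1319 stood at 48.4-fold on 554 ± 31.5 ends (SD, n = 3) beside SSU position 1318 at 15.6-fold on 171 ± 12.7, with deposited mean scores of 6.32 and 0.61. SSU positions 1051, 1052, 1053 and 1054 were called in a row, at 5.5-fold, 11.5-fold, 15.6-fold and 27.7-fold. LSU5 positions 1691 and 1692 stood at 8.11-fold and 20.2-fold, and LSU3 positions 1344 and 1345 at 21.5-fold and 11.4-fold. The deposited score also jumps unlisted positions, as at 2 positions picked after their values were seen: LSU3 position 583 has a score of 126 where reading the unlisted neighbour as 0 gives 170, and LSU5 position 678 has 3.12 in place of 25.0, while 21 scores in all move by more than 1.5 times.

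The adjacent pairs were weighed first. Chance placement stays open: random draws of as many tested positions per molecule gave 16.5 ± 3.79 pairs (SD over 10000 draws), and a share of 0.38 had at least the observed 18. A run of 4 was as long in a share of 0.066 of the draws, which also leaves chance open. An incomplete last cycle might leave a shoulder 1 position to the 3′ side of a site. In 8 of the 18 pairs, however, the 3′ member was the higher in every library. This argues against a shoulder on the 3′ side as the source of those 8. A shoulder on the 5′ side was not tested, so the 8 are not shown to be pairs of separate sites. In 1 of them, SSU position 2047 held 33.7 ends beside 912 at SSU position 2048. The 8 include the pairs within the run of SSU positions 1051 to 1054, which share members and are not separate observations. In 9 pairs the 3′ member was the lower in every library. At the 95 strong sites (16-fold or more) with both neighbours, the median count was 12.3 on the 3′ side and 6.33 on the 5′ side. The ratio was 1.82 after adding 1 count (95% bootstrap interval 1.29 to 2.38). That interval lies above equal counts but spans the 1.5 set as the limit, so a shoulder on the 3′ side stays open for the other pairs. No biological explanation was tested, since the design has 1 group.

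The larger share of tested positions called in LSU3 (odds ratio 1.42) may follow from its thin background, whose median flank was 15.0 ends against 26.0 in LSU5, 20.1 in SSU and 14.5 in 5.8S. With tested positions stratified into 10 groups by background the odds ratio was 1.0 (95% interval 0.763 to 1.32), as this explanation requires. That value cannot tell a thin background from the count minimum as the source. The background is also the denominator of the fold that defines a call, and the minimum acts most where it is thin. The count minimum, which removes weak positions where the background is thin, could not be settled as a separate source: over all positions the ratio was 1.19 (0.918 to 1.55). In order of rising median flank, the odds ratios over tested positions were 2.92 for 5.8S, 1.42 for LSU3, 0.886 for SSU and 0.712 for LSU5. Only LSU3 was stratified, so whether the background also accounts for the values of 5.8S and LSU5 was not tested. No biological explanation was tested.

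LSU5 position 1782, picked after its values were seen, is the last listed position of its molecule and the 26th site by fold, at 63.0-fold on 647 ± 12.7 ends (SD, n = 3), with a deposited score of 86.0 taken from 1 neighbour. Its background came from 1 side, and this stays open as a source: the lower fold of 45.3 with 12 flank positions or 5 added counts brings in nothing from the missing side. Carry-over of the natural 3′ ends of all rRNA molecules also stays open, because the true ends are not known here. The last listed positions of 5.8S, SSU and LSU3 held means of 3.0, 1.0 and 36.0 ends and none was above 4-fold, but 2 of these 3 molecules had a called site just before, 5.8S position 162 at 9.24-fold and LSU3 position 1526 at 10.8-fold, both also picked after their values were seen. An end of LSU5 alone that resists oxidation, and a methyl group on its last nucleotide, both stay open and were not tested.

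The hypothesis that strong sites crowd together was not borne out. The fullest window of 150 positions, LSU3 492 to 641, held 10 of the 96 strong sites, and a share of 0.13 of 10000 random placements within the molecules had a window as full.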
